A study of Solanum lycopersicum with 6 samples.

How the data were processed

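RNA was extracted from mature green fruits of Micro-Tom tomato with TRIzol and cleaned on RNeasy columns, and biotin-labelled cRNA was made from 100 ng of total RNA, per the labels' protocols. The design text speaks of ripening plants and the tissue label of mature green fruit. Samples were grouped by their titles into 3 control and 3 drought arrays. In the control group a fertilizer solution diluted 500-fold was used, and in the stress group the same dilution once a week, per the labels. Nothing in the labels says that the samples of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

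The deposited values are probe set summaries that the authors made, taken as log2 from the values themselves, since they run from 5.46 to 15.8 and stay below 16, the log2 of the highest reading of a common scanner. The method of background correction, normalization and summary is not given in the sources used here. The array medians were 7.8974, 7.9009, 7.9021, 7.9051, 7.9048 and 7.9072 for control replicates 1 to 3 and drought replicates 1 to 3. The range over the 6 arrays was under 0.001 in 75.71% of the probe sets, and 27 bacterial and phage spike-in probe sets had ranges of at most 0.00047. Log2 differences are therefore given on the scale of the deposited values and may not equal measured folds, and moderation across probe sets with such different spreads can affect which of them are called. For arrays, their number limits the precision.

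The table held 10209 probe sets. The 108 control probe sets of the array maker were left out and 10101 were tested, among them 63 reporter probe sets. Gene symbols came from the platform annotation. Of the tested probe sets, 909 had exactly 1 gene symbol, 0 had several and 9192 had none, and 885 of the probe sets had a gene identifier found in a RefSeq gene table (assembly SLM_r2.1), which changed 0 symbols. Of the genes, 176 have only a LOC identifier. Neither table gave gene descriptions and locus tags were not matched, so list membership rested on symbols and synonyms. Genes known only by description or locus tag were missed. No coordinates are given, since the build behind the array is not named. Of 82 genes with several probe sets, 21 had probe sets on both sides of 0, in 1 of them with a difference of 0.1 or more.

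Drought was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all tested probe sets, threshold 0.05), on the values as deposited, with no block and no filter. Gene lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists, 1 probe set per gene, the brightest on average) against the 803 named genes, with an estimated correlation and fry as alternatives. The 20 lists, fixed before the data were examined, covered ripening regulators and effectors, ethylene, carotenoids, cell wall, photosynthesis, abscisic acid, dehydrins with LEA and ASR proteins, heat shock proteins, compatible solutes, sugars and starch, GABA and nitrogen, phenylpropanoids, antioxidants, steroidal alkaloids and sterols, jasmonate and defence, aquaporins, histones and cell division, ribosomal proteins, cuticle and epidermis, and seed storage proteins. The 16 lists with at least 3 members were tested.

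The rule for naming genes was also fixed before the data were examined. It took the 12 largest rises and 12 largest falls among called probe sets with 1 gene symbol whose arrays did not overlap between groups (or all, where fewer passed), up to 3 called members of each list or otherwise the 2 with the smallest p, and RIN, NOR, CNR, E8, E4, PG2, PSY1, ACS2, ACS4, ACO1, NCED1, TAS14, ASR1, PRO2 (the P5CS gene) and LE25 where the array holds a probe set under that name. CNR, E4, ACO1, ASR1 and LE25 were not analysed here under these names. The procedure was tested on simulated arrays with each probe set's own SD and 200 changed among 10101 probe sets for drought against control. It recovered 48 of 50 changes of 0.01, 47 of 50 of 0.1, 50 of 50 of 1 and 50 of 50 of 2 on the log2 scale, with 9 false calls. The simulation gives changes no link to the spread, whereas in the arrays the probe sets with large differences also had large spreads.

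Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 30% of probe sets, the replicate number as a block, a trended robust prior, array weights, leaving out each array in turn, averaging the probe sets of a gene, unmoderated variances and unadjusted p-values. Another pseudocount was not run, since the values were already logarithms. All 15 pairs of arrays held at least 47 probe sets that differed by over 0.1, so no array was counted as a copy of another.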

Results

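Transcript levels were measured in mature green fruits of the dwarf tomato cultivar Micro-Tom from plants kept under normal conditions and from plants kept under drought. Each group held 3 arrays, and each array was hybridized with biotin-labelled cRNA in 1 colour. The fruits came from a greenhouse held at 25 °C by day and 20 °C in the evening and were picked 30 to 40 days after flowering. The stressed plants received the fertilizer solution once a week, so water and nutrient supply were tied together in the treatment. The value table gave 10101 probe sets for the comparison, of which 909 (9.0%) carried a gene symbol, for 803 genes. The question put to the data was which fruit transcripts differed between drought and control.

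Within the deposited values, the 3 drought arrays lay close together and the 3 control arrays did not. The first principal component held 90.95% of the variance and placed the drought arrays at 7.02, 6.81 and 6.93, control replicates 1 and 2 at -12.38 and -10.28, and control replicate 3 at 1.90. The values were not scaled, and 90.74% of the probe sets had a range under 0.01. This component therefore rests mainly on the few probe sets that moved most. Across probe sets, which are not independent replicates, control replicate 3 correlated more closely with the drought arrays (Pearson's r 0.9990 to 0.9992) than with control replicates 1 and 2 (0.9960 and 0.9970). Most probe sets hardly moved at all. The median range over the 6 arrays was 0.00013 on the log2 scale, and 268 probe sets had a range over 0.1. Bacterial and phage spike-in probe sets had a median range of 9.1e-05, so a difference on this scale may not equal a fold change as measured by a scanner.

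In the comparison as deposited, fruits of drought plants had higher values of DFR, which encodes dihydroflavonol reductase of the anthocyanin pathway, and of the transcription factor gene TCP3. DFR rose by 0.11 ± 0.0086 (SE) on the log2 scale, from 6.16 ± 0.015 to 6.27 ± 0.0044 (SD, n = 3 each, limma adjusted p = 0.0443). DFR lay below the 25th percentile of every array (6.63 to 6.64) and had no value once the dimmest 30% of probe sets were left out. TCP3 rose by 0.031 ± 0.0028 (SE, adjusted p = 0.0464). The pectin methylesterase gene PME2.1 fell by 0.014 ± 0.0013 (SE, adjusted p = 0.0482), and BL2 fell by 0.011 ± 0.00070 (SE, adjusted p = 0.0388). The rule that named these genes required all 3 drought arrays to lie on one side of all 3 control arrays. Their direction was the same after quantile normalization and after centring. None of these 4 calls held after quantile normalization (adjusted p = 0.0521 for DFR, 0.0550 for TCP3, 0.0725 for PME2.1 and 0.0723 for BL2), with the replicate number as a block (0.112 to 0.188) or without any one of the 5 arrays other than control replicate 3.

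In all, 77 probe sets passed an adjusted p of 0.05 in limma, 53 higher and 24 lower in drought. Their absolute log2 differences ran from 4.3e-05 to 0.11 with a median of 0.00061, and 7 of them had a gene symbol. The other named ones were TAL (+0.00034 ± 2.2e-05, SE, adjusted p = 0.0410), the heme oxygenase gene HO2 (+4.3e-05 ± 4.3e-06, adjusted p = 0.0495) and the auxin response factor gene ARF3 (-0.00015 ± 1.4e-05, adjusted p = 0.0482). In size, the differences of TAL, HO2 and ARF3 lay under the largest range of a spike-in probe set over the arrays (0.00047). That of HO2 also lay under the median spike-in range (9.1e-05). Variation of this size was thus also present in probe sets for no tomato gene. The median called difference of 0.00061 lay above the largest spike-in range. It lay under the median range of 14 tomato housekeeping control probe sets (0.00079). TAL and HO2 turned to lower in drought after quantile normalization (-0.0041 and -0.0033) and after centring each array on its median (-0.0052 and -0.0055), while ARF3 stayed lower. No probe set passed the limma threshold with a log2 difference of 1 or more, against 14 of that size at an unadjusted p under 0.05. At an unadjusted p under 0.05 there were 2524 probe sets, 1603 higher and 921 lower. The count rested on single arrays. It was 546 (377 higher, 169 lower) without control replicate 3, 7 without control replicate 1, 0 without control replicate 2, 1 without drought replicate 1 or drought replicate 2, and 0 without drought replicate 3. Adjusted p-values given below without control replicate 3 thus leave out the control nearest the drought arrays. Among single arrays left out, it is the one that gave the most calls. The count was 0 after quantile normalization and 9406 (214 higher, 9192 lower) after centring, where the array medians differed by at most 0.0098 but most probe sets by far less.

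**Figure D1:**
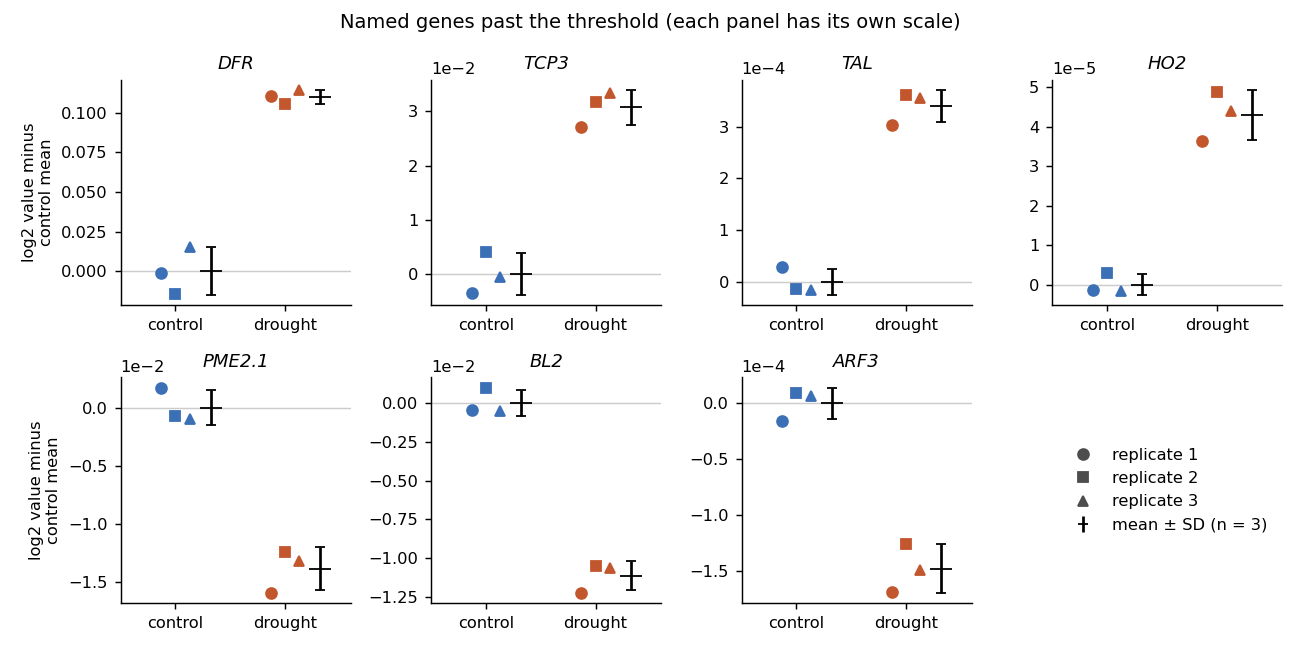
Log2 value minus the mean of the control arrays (y axis, a scale of its own in each panel) for the 7 named genes past the threshold, in control and drought arrays (x axis). Symbols are single arrays and bars give the mean ± SD of n = 3. The drought mean of DFR lies 0.11 above the control mean and that of HO2 4.3e-05 above it.

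Counting probe sets whose 3 drought values all lay beyond all 3 control values does not depend on the size of a difference. There were 3511 such probe sets (34.76%), 2068 higher and 1443 lower in drought, where chance gives 10% for a single probe set. Probe sets of an array are not independent, so this share is no test of the labels. The medians of the drought arrays (7.9048 to 7.9072) also all lay above those of the control arrays (7.8974 to 7.9021). Among the 803 named genes, 145 (18.06%) were separated upward and 138 (17.19%) downward. The count depended on scaling. It was 3786 after quantile normalization and 9480 after centring each array on its median.

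No dehydrin or LEA gene and no abscisic acid gene passed the test over all probe sets. The list of dehydrins, LEA and ASR proteins held 4 genes here, none of them under an ASR name. Of these, LE16 (-0.0052, limma adjusted p = 0.429) encodes a lipid transfer protein and was also counted among the cuticle genes below. The list's values thus do not rest on dehydrin and LEA genes alone. All 4 had lower means in drought, and 0 passed adjusted over the list alone. The LEA-like gene ER5 had a difference of -0.33 ± 0.15 (SE, adjusted p = 0.264), with control values of 8.99, 9.06 and 8.62 and drought values of 8.52, 8.44 and 8.70. LEA14 (-0.0039, adjusted p = 0.200) and the dehydrin gene TAS14 (-0.15 ± 0.091, SE, adjusted p = 0.379, at -0.23 without control replicate 2 and -0.098 without control replicate 3) also missed the threshold. The list's median difference was -0.079 (camera adjusted p = 0.208), at -0.12 without control replicate 2 and -0.051 without control replicate 3, whereas the directional fry test, which does not set a list against other genes, gave an adjusted p of 0.00828. Of the 4 abscisic acid genes, 0 passed over all probe sets and 1 adjusted over the list alone, the zeaxanthin epoxidase gene ZEP (-0.0025, adjusted p = 0.111 over all). NCED1, the gene of the dioxygenase that cleaves epoxycarotenoids toward abscisic acid, differed by -0.00060 ± 0.00026 (SE, adjusted p = 0.255). FLACCA had a higher mean in drought with all arrays separated (+2.1e-05, adjusted p = 0.391, at 7.8e-06 without control replicate 2). After each array was centred on its median, ER5 (-0.34, adjusted p = 0.0408), LEA14, ZEP and NCED1 (adjusted p = 0.0201 each) passed, as most probe sets did.

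Of the 4 genes for proline and other compatible solutes, 0 passed over all probe sets and 1 adjusted over the list alone. That gene was PRO2, which encodes a pyrroline-5-carboxylate synthetase (+3.9e-05 ± 4.0e-06, SE, adjusted p = 0.0506, 0.0520 without control replicate 3, below 0 after quantile normalization and after centring). Of 2 genes that share the symbol PRO1, the one with the smaller p differed by -0.00023 (adjusted p = 0.191). Camera gave adjusted p = 0.473 for the abscisic acid list and 0.774 for the solute list. The small heat shock protein genes vis1 (-0.0031, adjusted p = 0.462) and HSP21 (-0.042, adjusted p = 0.530) and the aquaporin gene Aqp2 (+0.0011, adjusted p = 0.588, below 0 after quantile normalization and after centring) missed the threshold too, and their lists of 2 genes and 1 gene were too short to test. Without control replicate 1 the differences shrank to -0.00089 for vis1, -0.010 for HSP21 and 0.00029 for Aqp2.

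On the values as deposited, of the 16 ripening regulators and effectors, 0 passed over all probe sets and 0 adjusted over the list alone, and 11 had lower means in drought (camera adjusted p = 0.774). RIN, a MADS-box regulator of ripening, differed by -0.14 ± 0.058 (SE, adjusted p = 0.232), from 6.08 ± 0.10 in control to 5.94 ± 0.0063 in drought (SD, n = 3 each), with all drought arrays below all control arrays, and by -0.080 without control replicate 1. The MADS-box gene TDR4 (-0.018, adjusted p = 0.143) and the galactosidase gene TBG4 (+0.0019, adjusted p = 0.151, below 0 after quantile normalization and after centring) had the smallest p-values of the list. NOR (-0.0043, adjusted p = 0.895) and E8 (-0.023, adjusted p = 0.892) turned positive without control replicate 1 (0.0094 and 0.046). The phytoene synthase gene Psy1 differed by -0.0045 ± 0.0042 (SE, adjusted p = 0.576) and by -0.00053 without control replicate 1, and the polygalacturonase gene PG2 by -2.1e-06 (adjusted p = 0.612), positive after quantile normalization. The 3 probe sets of Psy1 ran from -0.0045 to -3.0e-05. RIN and PG2 lay below the 25th percentile of every array (6.63 to 6.64). Of the 16 genes, 11 had values once the dimmest 30% of probe sets were left out. After centring, RIN (-0.15, adjusted p = 0.0300), TDR4 and PG2 (adjusted p = 0.0201 each) passed, as most probe sets did.

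Of the 24 genes of ethylene synthesis and signalling, 0 passed, 0 adjusted over the list alone (camera adjusted p = 0.473). EIL1 (-0.00049, adjusted p = 0.10) and the receptor gene ETR1 (-3.5e-05, adjusted p = 0.104) came nearest. The ACC synthase genes ACS4 (-0.00040, adjusted p = 0.416, at -0.00020 without control replicate 1) and ACS2 (+9.8e-06, adjusted p = 0.907) missed the threshold, and ACS2 turned negative after centring and without control replicate 2 or control replicate 3. ACS2 also lay below the 25th percentile of every array. Of the 13 carotenoid genes, 0 passed over all probe sets and 1 adjusted over the list alone, the phytoene desaturase gene PDS (+0.0016 ± 0.00018, SE, adjusted p = 0.0526, 0.0495 without the dimmest probe sets and 0.0443 with array weights, below 0 after quantile normalization and after centring). The camera adjusted p of the carotenoid list was 0.829.

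Of 21 cell wall genes, PME2.1 fell, 20 missed the threshold over all probe sets, and 4 passed adjusted over the list alone, with 2 higher and 2 lower (camera adjusted p = 0.513). The galactosidase genes TBG7 (+0.072 ± 0.0096, SE, adjusted p = 0.0539) and TBG5 (+0.015, adjusted p = 0.0836) were the higher ones, and PE1 (-0.00041, adjusted p = 0.0711) was lower beside PME2.1. These 3 and the next were picked after their values were seen. The xyloglucan endotransglucosylase gene XTH3 differed by -0.40 ± 0.25 (SE, adjusted p = 0.403), at -0.25 without control replicate 2 and -0.60 without control replicate 3, and its relative XTH16 by +0.21 ± 0.088 (adjusted p = 0.239), at 0.12 without control replicate 1. The 3 probe sets of XTH16 ran from 0.078 to 0.21.

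Defence genes included the largest differences among the lists, none past the threshold over all probe sets. Of 25 jasmonate, wound and pathogenesis-related genes, 5 passed adjusted over the list alone, 1 higher and 4 lower, and 17 had lower means in drought (camera adjusted p = 0.0967). The osmotin-like gene NP24-I was at 7.23 ± 0.097 in control and 6.80 ± 0.040 in drought (SD, n = 3 each), a difference of -0.42 ± 0.058 (SE, limma adjusted p = 0.0547, and 0.0419 without control replicate 3). The chitinase gene CHI17 differed by +0.0024 (adjusted p = 0.0598, 0.0279 without control replicate 3, below 0 after quantile normalization and after centring). Picked after their values were seen, the glucanase gene GluB differed by -0.66 ± 0.23 (SE, adjusted p = 0.188), PR1b1 by -0.46 ± 0.32 (adjusted p = 0.446, at -0.16 without control replicate 2), the chitinase gene CHI9 by -0.20 ± 0.043 (adjusted p = 0.0920) and the threonine deaminase gene TD2 by +0.65 ± 0.27 (adjusted p = 0.237, and 0.0388 without control replicate 3). Without control replicate 3 the limma adjusted p was 0.278 for GluB, 0.349 for PR1b1 and 0.122 for CHI9. The other probe set of PR1b1 differed by -1.2e-06. TD2 stood at 7.38 in control replicate 3 against 6.53 and 6.59 in the other controls, near its drought values of 7.35, 7.61 and 7.49.

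**Figure D2:**
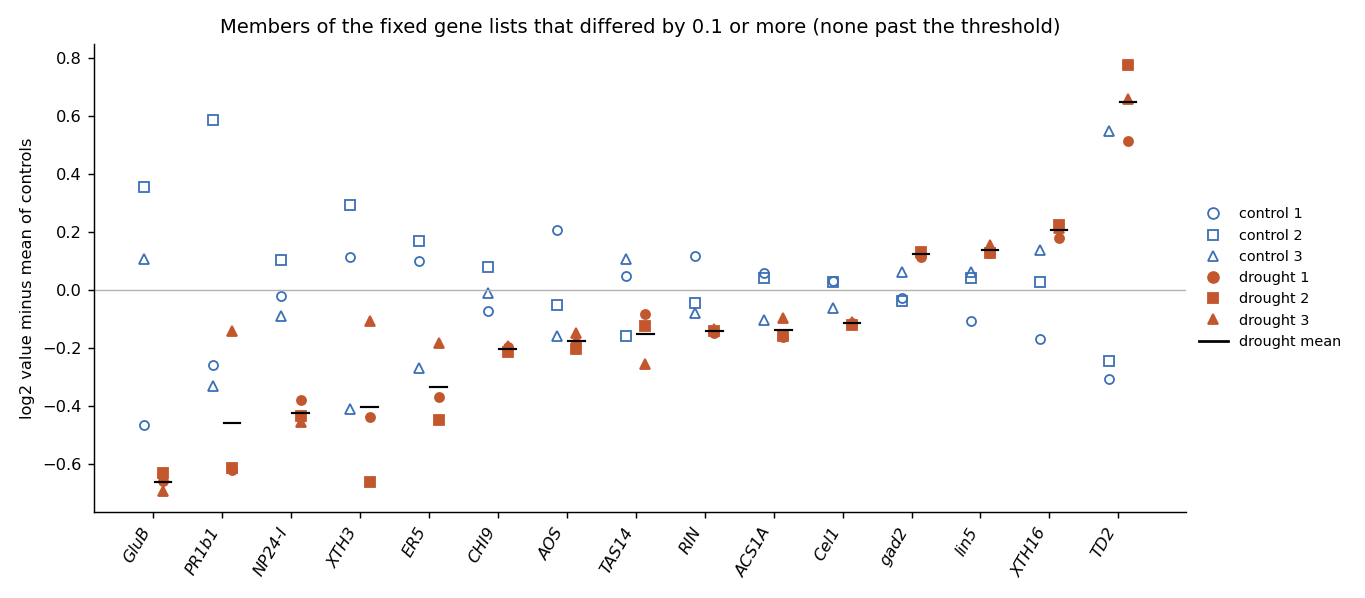
Log2 value minus the mean of the control arrays (y axis) for the 15 members of the fixed gene lists with an absolute difference of 0.1 or more and no call (x axis), ordered by difference. Open symbols are control arrays, filled symbols drought arrays and lines the drought mean, from -0.66 for GluB to 0.65 for TD2.

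Of 10 cell division genes, 8 had higher means in drought and 0 passed over all probe sets, while 4 passed adjusted over the list alone, all higher. The camera adjusted p of 0.0692 was the lowest of the 16 lists tested (0.594 with an estimated correlation). The cyclin-dependent kinase gene CDKB2 differed by +0.034 ± 0.0060 (SE, adjusted p = 0.0722) and the cyclin gene CycA1 by +0.018 ± 0.0037 (adjusted p = 0.0867). The list's median difference was 0.0018, and -0.0037 after centring. Of 3 cuticle and epidermis genes, LE16 among them, which mark another cell layer of the fruit, 0 passed over all probe sets and 2 adjusted over the list alone, both lower (camera adjusted p = 0.0967). These were the lipid transfer protein genes TSW12 (-0.020 ± 0.0033, SE, adjusted p = 0.0636) and ltpg1 (-0.0051, adjusted p = 0.123). The 3 chlorophyll-binding protein genes found by symbol, which mark green tissue, had 0 calls, 0 adjusted over the list alone (camera adjusted p = 0.833). CAB5 differed by -0.022 ± 0.067 (SE, adjusted p = 0.895) and CAB6A by -0.00061 (adjusted p = 0.929), and both turned positive without control replicate 3 or drought replicate 3, as CAB6A did with array weights.

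In sugar metabolism, 0 of 22 genes passed over all probe sets and 1 adjusted over the list alone (camera adjusted p = 0.473). This was the hexose transporter gene HT3 (+0.00061, adjusted p = 0.0605, 0.0408 without control replicate 3), which with the hexokinase gene Hxk2 (+8.0e-05, adjusted p = 0.137) fell below 0 after quantile normalization and after centring. Of 11 GABA and nitrogen genes, 0 passed, 0 adjusted over the list alone (camera adjusted p = 0.530). The record named gad2, which also carries names of a steroidal alkaloid enzyme, differed by +0.12 ± 0.031 (SE, adjusted p = 0.112, and 0.0158 without control replicate 3), and the aminotransferase gene GABA-TP2 by +0.011 ± 0.0027 (adjusted p = 0.106). Both genes were also counted among the 3 of steroidal alkaloid and sterol synthesis, where 0 passed over all probe sets and 2 adjusted over the list alone (camera adjusted p = 0.294). Without control replicate 3 the limma adjusted p was 0.0519 for GABA-TP2 and 0.0801 for Hxk2.

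Of 6 phenylpropanoid and flavonoid genes, DFR rose and 5 missed the threshold, with 1 adjusted over the list alone (camera adjusted p = 0.473). Of 14 antioxidant genes, 0 passed, 0 adjusted over the list alone (camera adjusted p = 0.473), and GSH2 (-6.9e-05, adjusted p = 0.124) and the catalase gene cat1 (-0.0022, adjusted p = 0.220) had the smallest p-values. Over the 16 lists tested with camera, 0 passed with the preset correlation, 0 with an estimated one, and 3 had an unadjusted p under 0.05. No ribosomal or seed storage gene carried a symbol that matched those lists, which hold 0 members here.

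The 3 largest differences were found in probe sets without a gene symbol and missed the threshold over all probe sets. Group means differed by 1 or more on the log2 scale in 23 probe sets, most of them without a symbol, with 22 higher and 1 lower in drought and a lowest limma adjusted p of 0.0506. The probe set with the largest upward difference stood at 7.61, 7.61 and 14.61 in control and at 15.73 ± 0.099 (SD, n = 3) in drought (difference 5.79 ± 2.23, SE, adjusted p = 0.211, and 0.00195 without control replicate 3). The next one differed by 4.79 ± 1.45 (adjusted p = 0.150, 0.00369 without control replicate 3). The single lower one stood at 13.44, 12.03 and 11.86 in control and 6.59, 7.55 and 6.43 in drought (difference -5.59 ± 0.59, SE, adjusted p = 0.0506, 0.0419 without control replicate 3). These probe sets were picked after their values were seen. Without control replicate 3, 20 probe sets passed the threshold at this size, 19 higher and 1 lower. Without any other single array, 0 passed at this size.

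**Figure D3:**
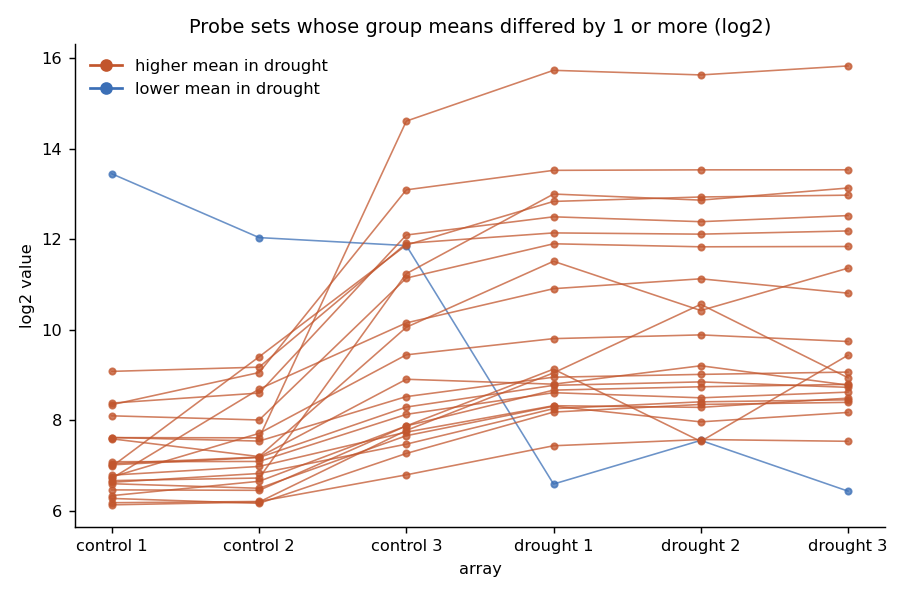
Log2 value (y axis) in each of the 6 arrays (x axis) of the 23 probe sets whose group means differed by 1 or more, a line joining the values of one probe set. Colours mark the 22 with a higher and the 1 with a lower mean in drought. Control replicate 3 lies between the other controls and the drought arrays in most of them.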

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

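The count of probe sets whose arrays did not overlap, its alternatives, estimated correlations under other alternatives and the run without reporter probe sets were chosen after the data were seen, and the other alternatives before. Over 550 values of named genes under the alternatives, 441 kept their direction and side of the threshold, 48 lost the call in the same direction, 32 gained one in the same direction and 29 changed sign, of which 2 also lost and 5 also gained a call. In all, 50 lost and 37 gained a call, 26 of the gains after centring, and 249 of 271 list values stayed on their side. The 7 called genes kept their calls without reporter probe sets, with array weights and without control replicate 3. Of these, 5 kept them without the dimmest probe sets, where DFR and HO2 had no value. All 7 lost them after quantile normalization, under the replicate block and without any one of the other 5 arrays. No detection call or background level was used here, so signal over background was not assessed.

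The number of called probe sets (77) became 0 after quantile normalization, 9406 after centring, 391 with array weights (301 higher, 90 lower), 7 with unmoderated variances, 2524 at an unadjusted p under 0.05, and 0 to 546 when single arrays were left out, highest without control replicate 3. It was 73 without the dimmest probe sets, 61 with a trended robust prior and 76 with the probe sets of a gene averaged. The number with a log2 difference of 1 or more (0) became 22 after centring, 1 without the dimmest probe sets, 4 with array weights and 0 to 20 without single arrays. Centring gave 9480 probe sets with arrays that did not overlap in place of 3511. By construction it lowered probe sets by a median of 0.0055 (shift of all probe sets, -0.0055), which exceeds most differences. Without control replicate 3, 5269 probe sets (52.2%) did not overlap, where chance gives 20% for a single probe set. For the other changes the cause was not tested.

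With the replicate number as a block 0 probe sets were called. The deviations of same-numbered arrays from their group means correlated at -0.092, -0.023 and -0.106, and no array correlated best with its own number, so the numbers were not taken as pairs. The block fit let the cell division list (median 0.0018) and the cuticle list (-0.0052) pass, though not with an estimated correlation (adjusted p = 0.665 each).

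After quantile normalization the signs changed for TAL (-0.0041), HO2 (-0.0033), TBG4 (-0.0022), PDS (-0.0016), PRO2 (-0.0015), HT3 (-0.0042), Hxk2 (-0.0033), CHI17 (-0.0019), Aqp2 (-0.0030) and PG2 (0.00018), and the GABA list (median -0.0015, with camera's direction upward), the alkaloid list (0.0054) and the cuticle list (-0.014) passed camera, though not with an estimated correlation (adjusted p = 0.579 each). After centring the signs changed for TAL (-0.0052), HO2 (-0.0055), TBG4 (-0.0036), PDS (-0.0039), PRO2 (-0.0055), HT3 (-0.0049), Hxk2 (-0.0055), CHI17 (-0.0031), Aqp2 (-0.0044) and ACS2 (-0.0055), and the GABA list (-0.0055, with camera's direction upward), the alkaloid list (0.0058) and the cell division list (-0.0037, with camera's direction upward) passed, though not with an estimated correlation (adjusted p = 0.861, 0.450 and 0.964). With array weights CAB6A was at 0.00032, and PDS, PRO2, HT3, NP24-I, CHI17 and TSW12 gained a call. Leaving out single arrays gave ranges of -0.061 to 0.027 for CAB5, -0.0017 to 0.0013 for CAB6A, -0.011 to 0.0094 for NOR, -0.058 to 0.046 for E8 and -8.9e-06 to 4.4e-05 for ACS2.

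The cell division list also passed with a trended robust prior (0.0018) and without drought replicate 1, its median running from 0.0015 to 0.0023 without single arrays, but neither held with an estimated correlation (adjusted p = 0.579 and 0.622). The fry test for change in either direction, which compares no list with other genes, passed for 11 lists at unchanged medians. These were ethylene (-6.6e-06), carotenoids (-7.3e-05), cell wall (-0.00025), abscisic acid (-0.00045), dehydrins (-0.079), solutes (1.4e-05), sugars (5.2e-05), GABA (5.6e-06), phenylpropanoids (0.00051), defence (-0.00029) and cell division (0.0018). Without control replicate 1, camera's direction turned upward for the ethylene and carotenoid lists. Directional fry passed for the dehydrin list (-0.079) alone.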

Other observations

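All tests of explanations here were chosen after the patterns had been seen, and the genes in the next paragraph were picked after their values were seen.

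Some genes outside the lists are given singly, as no list or count was tested for them, and none passed the threshold. The cold response regulator gene CBF1 differed by -0.21 ± 0.15 (SE, limma adjusted p = 0.436), the ethylene response factor gene PTI5 by -0.30 ± 0.21 (adjusted p = 0.457) and the kinase gene MPK3 by -0.13 ± 0.072 (adjusted p = 0.353). The 3 probe sets of MPK3 ran from -0.13 to -0.00094. Without control replicate 2 CBF1 was at -0.10 and MPK3 at -0.080, and without control replicate 3 CBF1 was at -0.32 and PTI5 at -0.47. Without control replicate 1 PTI5 was at -0.18 and TomloxE, given below, at -0.14. The xyloglucan endotransglucosylase genes XET2 (-0.36 ± 0.10, adjusted p = 0.134) and tXET-B2 (-0.23 ± 0.13, adjusted p = 0.342) and the lipoxygenase gene TomloxE (-0.23 ± 0.083, adjusted p = 0.196) were lower as well. The expansin gene exp18 differed by +0.11 ± 0.017 (adjusted p = 0.0633) and psi14B by +0.13 ± 0.018 (adjusted p = 0.0598) in 1 of its 3 probe sets, the others differing by +0.11 (adjusted p = 0.0539) and -2.5e-06 (adjusted p = 0.747). Among genes known only by a LOC identifier, LOC543646 was at 6.70 ± 0.93 in control and 9.51 ± 0.91 in drought (SD, n = 3 each, limma adjusted p = 0.117) and LOC543898 at 6.39 ± 0.35 and 7.51 ± 0.071 (limma adjusted p = 0.0696, and 0.0158 without control replicate 3). Without control replicate 3 the limma adjusted p was 0.0796 for LOC543646, 0.0850 for exp18 and 0.0679 for the first psi14B probe set given.

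Control replicate 3 stood apart from the other controls. Against control replicates 1 and 2 alone, 96 probe sets were higher in every drought array by a mean of at least 0.1 and 81 were lower. In the 96, control replicate 3 lay at a median of 0.58 of the way to the drought mean and reached the lowest drought array in 12.5%. Each drought array reached the lowest of the other drought arrays in 54.17% to 73.96%, a larger share than that of control replicate 3. In the 81, control replicate 3 lay at 0.91 of the way and reached the highest drought array in 69.14%. The drought arrays themselves gave 12.35% to 96.3% there, so the 81 cannot decide on the label. Unlike the drought arrays, control replicate 3 had no part in choosing these probe sets, which limits the comparison. The 96 therefore cannot decide on a wrong label either. Drought replicate 3 was the highest drought array in 87.65% of the 81, against 3.7% and 8.64% for drought replicates 1 and 2. A mixture of RNA of both groups would place control replicate 3 no further along in the 81 than in the 96. The difference was 0.33 (95% bootstrap interval 0.25 to 0.41, with probe sets drawn as if independent). It was 0.21 (interval 0.14 to 0.29) with the drought level taken without drought replicate 3. At minimum differences of 0.01, 0.05 and 0.3 the falls also lay further along. At a minimum of 1 the order turned, with median positions of 0.718 for 27 rises and 0.15 for the 1 fall. Small differences may have been compressed before deposit, so these positions cannot decide on a mixture. A difference between plants or in fruit age within the harvest window stays open and was not tested.

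The near identity of most values may come from processing before deposit. The 27 spike-in probe sets had a median range of 9.09e-05 over the 6 arrays, under the 0.01 set as a bound for signals that were hybridized and scanned separately, and this is consistent with compression of small differences. Deposit of one array several times would leave a pair without differences, but each pair held at least 47 probe sets that differed by over 0.1. No biological explanation was tested.

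Of the 10 splits of the 6 arrays into 3 and 3, only that of the labels gave 77 called probe sets, and the highest of the other splits gave 0. For probe sets with arrays that did not overlap, only the split of the labels reached 3511, and the highest of the others had 1344. A probe set can be separated in only 1 of the 10 splits, so a high count in 1 split lowers the others. With 10 splits no share under 0.05 can be had.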
